A study of Mus musculus with 24 samples.

How the data were processed

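Total RNA was extracted with TRIzol from mouse embryonic fibroblasts 2 or 7 days after mock treatment or retroviral transduction with GMT, GHMT or AGHMT, per the labels' protocols, and sequenced in 24 libraries, 3 in each of 8 groups. Groups and replicate numbers were taken from the labels. The design text also mentions embryonic heart and ChIP-seq, which were not analysed here. The submitters' processing notes name Trim Galore 0.4.1, HISAT2 2.0.1, featureCounts 1.4.6 and DESeq2 1.6.3 and the build GRCm38 (mm10), without a role or order. The annotation release, the strand setting and any filters are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene may therefore be counted together, and members of families with similar copies are uncertain. The deposited count table holds raw whole-number counts of reads for 47967 genes, of which 13946 had 0 counts in every library. All 37 genes named as mitochondrial were at 0 counts in the table, so the mitochondrial genome was not measured. The deposited log2 table was checked against the counts: it equals log2 of CPM, counts scaled by the library total, with values under 1 CPM set to 0, within 0.00603, and it was used only for this check.

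Library totals ran from about 29346000 to 37495200 counts, which limits precision for genes at a few counts. No pair of replicates agreed within sampling noise, since the lowest chi-square per degree of freedom over genes was 1.55, so each library counted as 1 replicate. Genes with enough counts by edgeR's filterByExpr were tested, 17576 in all, holding 99.9% of counts in the lowest library. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with 1 mean per group over all 24 libraries and 16 residual degrees of freedom. The common biological coefficient of variation was 5.55%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and tests were two-sided. The 14 comparisons were each cocktail against the mock of its day, GHMT against GMT and AGHMT against GHMT at each day, the day difference of each cocktail effect, and mock at day 7 against day 2. Levels are TMM-scaled CPM. Where a whole group was at 0 counts, a fold is a lower bound against 3 counts per library, which covers counting error only.

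Before the data were examined, 28 gene lists from textbook knowledge were fixed, besides the list of the 5 factors. They cover sarcomere, calcium handling and ion channels, cardiac transcription factors, atrial and natriuretic, ventricular, pacemaker, fibroblast and matrix, smooth muscle and myofibroblast, TGF-beta and YAP response, skeletal muscle, S phase, G2 and M phase, p53 targets, fatty acid oxidation, oxidative phosphorylation, glycolysis, sterol and fatty acid synthesis, FoxO targets, ATF4 and amino acid response, interferon response, inflammatory response, and EGF receptor and ERK response. Markers of other cell types were macrophage, endothelial, epithelial and mesothelial, neural and glial, cartilage and bone, and adipocyte. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 28 lists of a comparison. Camera compares a list with the other genes. It was repeated with the correlation estimated for each list, and fry tested whether a list moved on balance one way.

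Genes named in the text came from a rule fixed before the data were examined. It took the 5 factors, the 8 genes with the highest and the 8 with the lowest fold change against mock (4 and 4 in other comparisons) among called genes of at least 5 CPM in the higher group whose replicates did not overlap, and up to 4 members of each called list, or members of a list whose count is described, by smallest adjusted p. Unnamed gene models and pseudogenes were left out, and some results on chosen genes are not reported here. Coordinates, GC content and length came from GENCODE M21 on GRCm38, which matched 47601 genes and 99.7% of those tested.

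The code was tested on simulated counts modelled on AGHMT against mock at day 7, with 16085 genes. Of 50 genes changed at each size, 42% were recovered at 1.2-fold, 90% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 8 of 15885 unchanged genes were called. Only these genes changed and each gene was drawn independently, so the rates do not describe comparisons in which most genes move. The alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, no filter on low counts, only the compared libraries, each library left out, the replicate number as a block, camera with an estimated correlation, and fry. Offsets for GC content and length, and leaving out the 3 libraries furthest from their groups, were added after the data had been seen.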

Results

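RNA sequencing was used to read out gene expression in mouse embryonic fibroblasts (MEFs), connective-tissue cells grown from C57BL/6 embryos, after retroviral delivery of factor cocktails that push fibroblasts towards a heart muscle identity. The series was set up to study the mechanism of this cardiac reprogramming. The cocktails are named by letters that usually stand for Gata4, Mef2c and Tbx5 (GMT), for these with Hand2 (GHMT), and for GHMT with Akt1, a kinase of growth factor signalling (AGHMT). Mock-treated fibroblasts were the control, and the labels do not state whether they received an empty virus. RNA was taken 2 or 7 days after transduction, in 8 groups of 3 libraries, 24 in all. The libraries held about 29346000 to 37495200 counted reads each, with 22720 to 24422 genes at 1 count or more. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels give no batch, so a batch that followed cocktail or day could not be told apart from it. Levels are in CPM, the usual unit of counts scaled to library size, as mean ± SD over the 3 libraries of a group (n = 3 throughout), and differences are log2 fold changes ± SE. Counts of list members are over all genes tested, with the count adjusted over the list alone in brackets where it differs, and medians are of log2 fold changes.

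The genes of the cocktails were read first, since they check the labels. Gata4 (ENSMUSG00000021944, chromosome 14, 63198922-63271692 on GRCm38), Mef2c (ENSMUSG00000005583, chromosome 13, 83504034-83667080) and Tbx5 (ENSMUSG00000018263, chromosome 5, 119832668-119885219) were higher than in the mock of the same day under every cocktail, and so was Hand2 (ENSMUSG00000038193, chromosome 8, 57320983-57324633) under GHMT and AGHMT. At day 7, Gata4 stood at 1022 ± 28.1 CPM in GMT, 1142 ± 85.9 CPM in GHMT and 633 ± 5.18 CPM in AGHMT, against 1.399 ± 0.0953 CPM in mock. Tbx5 stood at 2327 ± 64.4 CPM, 2746 ± 62.01 CPM and 1730.2 ± 25.9 CPM in the same order, against 10.99 ± 0.607 CPM. Mef2c reached 1681 ± 50.3 CPM, 2016 ± 33.9 CPM and 1643 ± 20.7 CPM, against 33.1 ± 2.25 CPM. Hand2 was at 978 ± 42.1 CPM in GHMT and 1125 ± 10.9 CPM in AGHMT, while in GMT, which lacks it, it fell to 3.23 ± 0.199 CPM from 7.58 ± 0.411 CPM in mock. Akt1 (ENSMUSG00000001729, chromosome 12, 112653821-112674884) was high in mock too, at 385 ± 22.5 CPM at day 7. It was only slightly higher under AGHMT, at 451 ± 7.201 CPM at day 7 (log2 0.23 ± 0.04, edgeR, adjusted p = 2.40e-05) and 469 ± 17.7 CPM at day 2 (log2 0.28 ± 0.04, edgeR, adjusted p = 1.70e-06). Under GMT and GHMT, Akt1 differed from mock by log2 -0.08 to 0.02 and did not pass the threshold at either day. For Akt1, GMT versus mock, day 2, the difference (edgeR, adjusted p = 0.0905) passed it with the compared libraries fitted alone (0.0228), without the 3 libraries furthest from their groups (0.0378) or with offsets for GC content and length (0.00178). For Akt1, GHMT versus mock, day 7, it passed with those offsets (edgeR, adjusted p = 0.00131). All 24 pairs of a factor and a comparison in which the factor belonged to the cocktail were called higher than mock (edgeR). Gene counts hold viral and endogenous transcripts alike, and the files do not separate them.

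**Figure D1:**
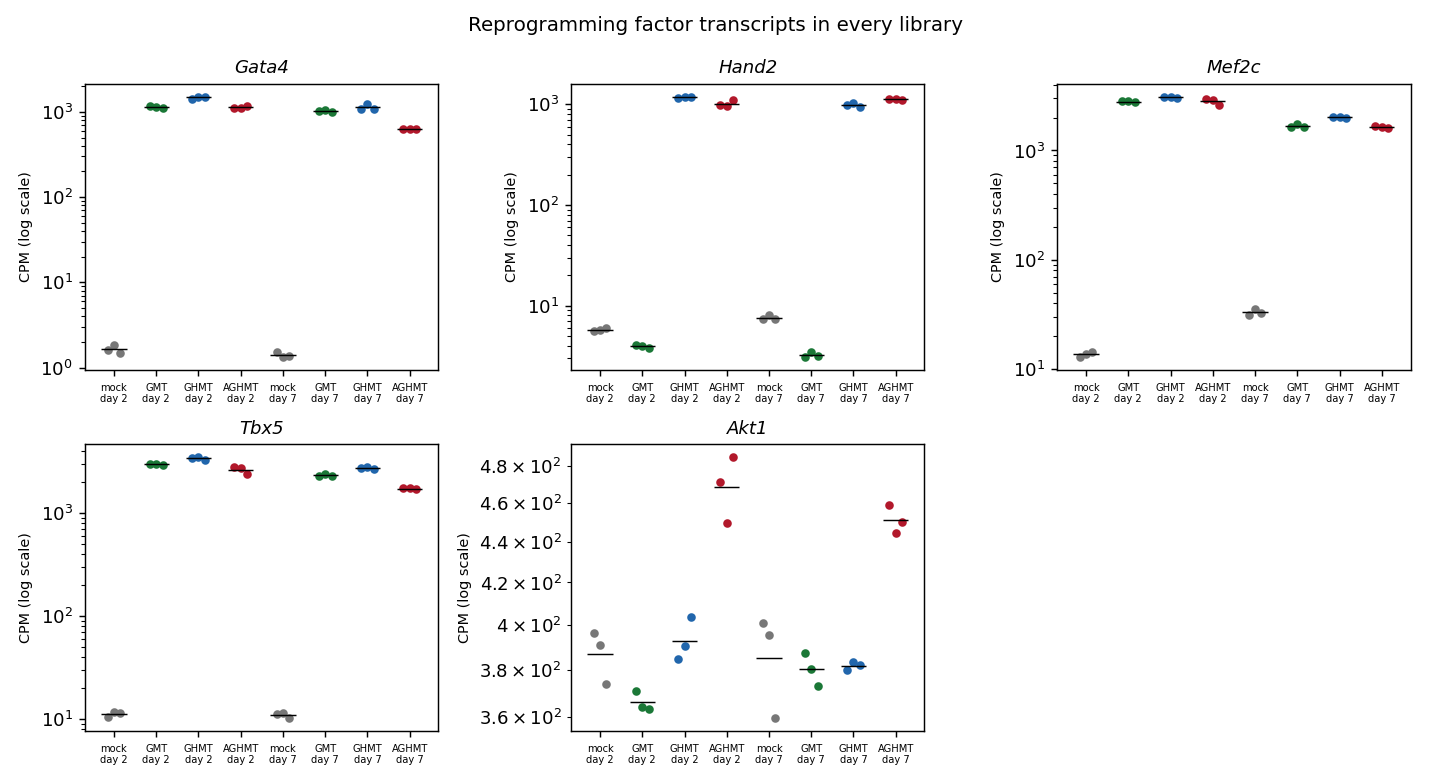
Level of the 5 factor genes in each of the 24 libraries, in CPM on a log axis, grouped by cocktail and day, where points are libraries and lines are group means. Gata4, Mef2c and Tbx5 lie far above mock in all 3 cocktails, Hand2 only in GHMT and AGHMT, and Akt1 lies between 359.5 and 485 CPM in every library.

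The effect of the fullest cocktail at the later time was read from AGHMT against mock at day 7. Several heart muscle genes that stood under 2 CPM in mock reached levels over 100 CPM. Of the cardiac sarcomere list, contractile and Z-disc proteins, 36 of 39 members rose, with a median log2 fold change of 7.57 (camera, adjusted p = 4.86e-19). Myh6 (ENSMUSG00000040752, chromosome 14, 54941921-54966927), the alpha myosin heavy chain of the heart, stood at 4610.3 ± 176 against 0.681 ± 0.323 CPM (log2 12.72 ± 0.15), although reads shared with the near-identical Myh7 beside it make its level uncertain. Actn2, the alpha-actinin of the Z-disc, stood at 466 ± 11.3 against 0.405 ± 0.101 CPM, and Mybpc3, cardiac myosin-binding protein C, at 503 ± 4.76 against 0.0820 ± 0.0763 CPM. Genes of calcium handling and ion channels moved the same way, as 30 of 35 members rose and 4 fell (31 rose and 4 fell adjusted over the list alone, median 3.86, camera, adjusted p = 2.92e-09). Casq2 (ENSMUSG00000027861, chromosome 3, 102086415-102146514), the calcium-binding protein of the sarcoplasmic reticulum, stood at 2164 ± 73.3 against 1.99 ± 0.170 CPM, and Trdn, triadin, at 156 ± 3.01 against 0.132 ± 0.0169 CPM. In the atrial and natriuretic list, 14 of 17 members rose and 3 fell (median 4.81, camera, adjusted p = 5.89e-05), with Myl7 (ENSMUSG00000020469, chromosome 11, 5896637-5898782), the atrial light chain 2, at 1072 ± 40.99 against 0.0816 ± 0.0196 CPM and Pam, a peptide-amidating enzyme, at 3426 ± 20.5 against 163 ± 5.54 CPM. That list includes Tbx5, which the cocktail delivers, and shares members with the sarcomere and calcium lists.

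Skeletal muscle genes rose as well, with 16 of 22 members higher and 1 lower (camera, adjusted p = 0.000516). Among them, Myl1, a fast-fibre light chain, stood at 740.3 ± 36.1 against 0.799 ± 0.122 CPM, Tnnt3, fast troponin T, at 89.1 ± 1.41 against 0.844 ± 0.148 CPM and Ryr1, the skeletal calcium release channel, at 32.97 ± 3.27 against 0.505 ± 0.0897 CPM. Transcription regulators of heart development outside the cocktail did not pass as a list, and 18 of 34 members rose and 13 fell (camera, adjusted p = 0.382). Nor did the ventricular list, where 7 of 12 members rose and 3 fell (camera, adjusted p = 0.137), the pacemaker list, where 8 of 17 members rose and 7 fell (camera, adjusted p = 0.792), or the smooth muscle and myofibroblast list, where 12 of 20 members rose and 6 fell (camera, adjusted p = 0.0866).

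Fibroblast genes fell. Of the fibroblast and matrix list, 41 of 44 members fell and 2 rose, with a median of -2.27 (camera, adjusted p = 1.99e-15). Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538-45349706), the collagen III chain, stood at 696 ± 20.2 against 12011 ± 649.6 CPM in mock, Lox, the lysyl oxidase that cross-links collagen, at 632 ± 26.4 against 5089.7 ± 117 CPM, Mmp2, a matrix protease, at 84.3 ± 4.78 against 853 ± 23.04 CPM, and Fbln5, fibulin 5 of elastic fibres, at 80.97 ± 0.527 against 1352 ± 28.8 CPM. Replication and division genes were also lower: 28 of 29 S phase genes fell (camera, adjusted p = 9.54e-09, or adjusted p = 0.171 with an estimated correlation), as did 28 of 29 G2 and M phase genes (camera, adjusted p = 2.92e-09, or adjusted p = 0.233 with an estimated correlation). Mcm6, of the replicative helicase, stood at 29.4 ± 2.13 against 84.7 ± 1.87 CPM and Ccna2, cyclin A2, at 12.04 ± 0.7895 against 45.99 ± 1.33 CPM. The single G2 and M phase member that rose was Cenpa, the histone variant of centromeres, at 155 ± 4.53 against 24.5 ± 0.216 CPM. Of the p53 targets, 15 of 22 members rose and 4 fell (camera, adjusted p = 0.00869, or adjusted p = 0.245 with an estimated correlation). The cell cycle inhibitor Cdkn1a stood at 1179 ± 7.26 against 517 ± 15.9 CPM and Ccng1 at 2894 ± 77.9 against 910.0 ± 59.3 CPM.

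Energy metabolism genes were higher. All 50 oxidative phosphorylation genes, nuclear subunits of the respiratory chain and ATP synthase, rose (median 0.95, camera, adjusted p = 2.66e-12, or adjusted p = 0.307 with an estimated correlation). Uqcrc2 stood at 211 ± 1.24 against 92.6 ± 0.721 CPM and Cox7a1, the muscle form of a cytochrome oxidase subunit, at 23.97 ± 0.567 against 0.5801 ± 0.142 CPM. In glycolysis, 20 of 23 members rose and 2 fell (camera, adjusted p = 1.51e-08, or adjusted p = 0.126 with an estimated correlation), with hexokinase 2 (Hk2) at 161 ± 5.15 against 21.3 ± 0.922 CPM and the muscle phosphofructokinase Pfkm at 215 ± 5.07 against 44.9 ± 1.09 CPM. In fatty acid oxidation, 19 of 25 members rose and 6 fell (camera, adjusted p = 0.00207, or adjusted p = 0.307 with an estimated correlation). Acsl1, an acyl-CoA synthetase, stood at 297 ± 7.56 against 13.1 ± 0.917 CPM and the thiolase Acaa2 at 596 ± 17.6 against 39.1 ± 2.85 CPM. The adipocyte list shared this direction, since 16 of 18 members rose and 2 fell (camera, adjusted p = 0.00280, or adjusted p = 0.138 with an estimated correlation). Pparg, the regulator of fat cell genes, stood at 11.8 ± 0.415 against 3.85 ± 0.129 CPM, whereas its member Lpl, lipoprotein lipase, fell to 94.6 ± 4.16 CPM from 362 ± 17.6 CPM. Genes of the ATF4 and amino acid response fell, 23 of 29 with 5 higher (camera, adjusted p = 0.000128, or adjusted p = 0.190 with an estimated correlation): the ATF4 target Trib3 stood at 7.92 ± 0.573 against 89.9 ± 5.27 CPM and Aldh18a1, of proline synthesis, at 54.7 ± 1.91 against 195 ± 3.94 CPM, while Stc2, stanniocalcin 2, rose to 193 ± 4.45 CPM from 17.3 ± 2.12 CPM.

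Macrophage markers were lower than in mock at the same day, where 21 of 21 members fell (median -3.46, camera, adjusted p = 3.73e-08, or adjusted p = 0.171 with an estimated correlation). Lyz2, the lysozyme of macrophages, stood at 21.7 ± 3.93 against 239 ± 45.3 CPM and Mrc1, the mannose receptor, at 1.13 ± 0.224 against 50.1 ± 10.2 CPM. In mock itself both rose between day 2 and day 7. The other lists passed no threshold. In the inflammatory list 16 of 29 members fell and 8 rose (camera, adjusted p = 0.216). In the interferon list 13 of 37 members fell and 8 rose (10 fell and 8 rose adjusted over the list alone, camera, adjusted p = 0.792). In the EGF receptor and ERK list 15 of 30 members fell and 11 rose (camera, adjusted p = 0.482). In the TGF-beta and YAP list 10 of 21 members fell and 8 rose (camera, adjusted p = 0.679). Among FoxO targets 14 of 25 members rose and 7 fell (14 rose and 8 fell adjusted over the list alone, camera, adjusted p = 0.326). For sterol and fatty acid synthesis 16 of 29 members fell and 8 rose (camera, adjusted p = 0.270). Of markers of other cell types, 8 of 17 endothelial genes rose and 5 fell (camera, adjusted p = 0.825), 9 of 15 epithelial and mesothelial genes fell and 4 rose (camera, adjusted p = 0.150), 8 of 18 neural and glial genes rose and 6 fell (camera, adjusted p = 0.774), and 8 of 19 cartilage and bone genes rose while 8 fell (camera, adjusted p = 0.825). In all, 13491 of 17576 tested genes passed the threshold, 6792 higher and 6699 lower, with 3205 higher and 2710 lower by at least 2-fold (edgeR, quasi-likelihood test). The list test called 14 of 28 lists, of which sarcomere, calcium, atrial, skeletal muscle and fibroblast held with an estimated correlation.

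GMT against mock at day 7 gave the effect of the smallest cocktail. The cardiac sarcomere list rose again, with 37 of 39 members higher and 1 lower (median 6.18, camera, adjusted p = 5.76e-19). Myom2, the M-band protein myomesin 2, stood at 1172 ± 46.2 against 0.506 ± 0.0763 CPM. Myl4, the atrial light chain 1, stood at 2817 ± 99.98 against 3.26 ± 0.314 CPM and Nppa, the atrial natriuretic peptide, at 589.9 ± 39.6 against 0.362 ± 0.183 CPM. In the atrial list 14 of 17 members rose and 3 fell (camera, adjusted p = 2.29e-05). Of calcium and channel genes, 24 of 35 members rose and 8 fell (camera, adjusted p = 9.73e-05). Casq2 stood at 204 ± 7.79 against 1.99 ± 0.170 CPM. Of the fibroblast and matrix list, 41 of 44 members fell and 2 rose (median -2.99, camera, adjusted p = 4.91e-19). Eln (ENSMUSG00000029675, chromosome 5, 134702593-134747323), elastin, stood at 3.31 ± 1.96 against 1688 ± 320.0 CPM in mock, Mfap4, a microfibril protein, at 1.52 ± 0.370 against 644 ± 53.8 CPM, and Col3a1 at 328 ± 6.37 against 12011 ± 649.6 CPM.

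Interferon-stimulated genes were higher under GMT than in the day 7 mock, with 34 of 37 members higher (35 higher adjusted over the list alone, median 1.44, camera, adjusted p = 4.00e-06, or adjusted p = 0.525 with an estimated correlation). Oas3, an antiviral RNA sensor of a family with similar copies, stood at 92.5 ± 5.84 against 1.19 ± 0.9505 CPM, and Irf7 at 161 ± 19.5 against 14.9 ± 6.43 CPM. The day 7 mock itself was lower in all 37 of these genes than the day 2 mock. Of the macrophage genes, 20 of 21 fell (median -3.60, camera, adjusted p = 3.75e-08, or adjusted p = 0.183 with an estimated correlation). In the EGF receptor and ERK list 21 of 30 members rose and 8 fell (camera, adjusted p = 0.00938, or adjusted p = 0.202 with an estimated correlation). The ligand Hbegf stood at 341 ± 16.97 against 18.3 ± 1.09 CPM and the feedback phosphatase Dusp6 at 137 ± 3.83 against 26.3 ± 0.470 CPM, but Spry1, another feedback inhibitor, at 11.8 ± 1.07 against 112 ± 6.94 CPM. Division genes fell, 28 of 29 in S phase (camera, adjusted p = 2.40e-09, or adjusted p = 0.182 with an estimated correlation) and 28 of 29 in G2 and M phase (camera, adjusted p = 2.15e-10, or adjusted p = 0.202 with an estimated correlation). Cenpa stood higher, at 207 ± 3.38 against 24.5 ± 0.216 CPM. Oxidative phosphorylation genes were higher, 48 of 50 (50 adjusted over the list alone, camera, adjusted p = 5.17e-09, or adjusted p = 0.440 with an estimated correlation). Glycolysis genes followed, 17 of 23 with 3 lower (median 0.82, camera, adjusted p = 0.000185, or adjusted p = 0.283 with an estimated correlation). In mock they fell between days (median -0.82). The muscle enolase Eno3 stood at 287 ± 5.62 against 16.02 ± 0.279 CPM. Of the adipocyte list, 16 of 18 members rose and 2 fell (camera, adjusted p = 0.00154, or adjusted p = 0.131 with an estimated correlation), and of the ATF4 list 22 of 29 members fell and 5 rose (camera, adjusted p = 0.000185, or adjusted p = 0.202 with an estimated correlation). In all, 12834 of 17576 tested genes passed the threshold, 6513 higher and 6321 lower, with 2760 higher and 2580 lower by at least 2-fold (edgeR). Camera called 16 of 28 lists, and sarcomere, calcium, atrial and fibroblast held with an estimated correlation.

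GHMT against mock at day 7 gave the effect of the cocktail with Hand2. In the sarcomere list 37 of 39 members rose (median 6.22, camera, adjusted p = 2.00e-20). Hspb7, a small heat shock protein of heart muscle, stood at 572 ± 9.402 against 7.56 ± 0.523 CPM. Casq2 stood at 2329.6 ± 97.9 against 1.99 ± 0.170 CPM, Kcnj5, an atrial potassium channel subunit, at 139 ± 4.95 against 0.0396 ± 0.0451 CPM, and Popdc2, a cyclic AMP-binding membrane protein of heart, at 268 ± 3.68 against 1.88 ± 0.178 CPM. Of the calcium and channel list 27 of 35 members rose and 6 fell (27 rose and 7 fell adjusted over the list alone, camera, adjusted p = 7.65e-07). In the atrial list 14 of 17 members rose and 3 fell (camera, adjusted p = 1.38e-05). Of fibroblast and matrix genes, 41 of 44 members fell and 3 rose (median -2.37, camera, adjusted p = 2.08e-17). The collagen I chain Col1a2 stood at 1595 ± 96.9 against 17643 ± 1050.5 CPM and the small proteoglycan Ogn at 7.58 ± 0.382 against 694 ± 22.03 CPM. Interferon genes stood above the low day 7 mock, with 34 of 37 members higher (camera, adjusted p = 6.95e-07, or adjusted p = 0.440 with an estimated correlation). Ifih1, a cytosolic RNA sensor, stood at 115 ± 6.45 against 20.8 ± 7.04 CPM. All 21 macrophage genes fell (camera, adjusted p = 3.96e-08, or adjusted p = 0.170 with an estimated correlation). Glycolysis genes stood above a low day 7 mock, 20 of 23 with 1 lower (median 0.73, camera, adjusted p = 7.65e-07, or adjusted p = 0.170 with an estimated correlation). The platelet phosphofructokinase Pfkp stood at 133 ± 5.38 against 30.6 ± 0.914 CPM. Likewise 45 of 50 oxidative phosphorylation genes rose (camera, adjusted p = 1.15e-06, or adjusted p = 0.474 with an estimated correlation). Sterol and fatty acid synthesis was called lower at the edge of the threshold, with 16 of 29 members lower and 6 higher (camera, adjusted p = 0.0471, or adjusted p = 0.474 with an estimated correlation). Against that direction, Scd1, a fatty acid desaturase, stood at 711 ± 56.3 against 170.5 ± 6.42 CPM. The call of the list was lost without mock replicate 1 (adjusted p = 0.0638), without GHMT replicate 2 (adjusted p = 0.0781) or with offsets for GC content and length (adjusted p = 0.0528). In all, 12648 of 17576 tested genes passed the threshold, 6387 higher and 6261 lower, with 2739 higher and 2487 lower by at least 2-fold (edgeR). Camera called 17 of 28 lists, and sarcomere, calcium, atrial and fibroblast held with an estimated correlation.

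**Figure D2:**
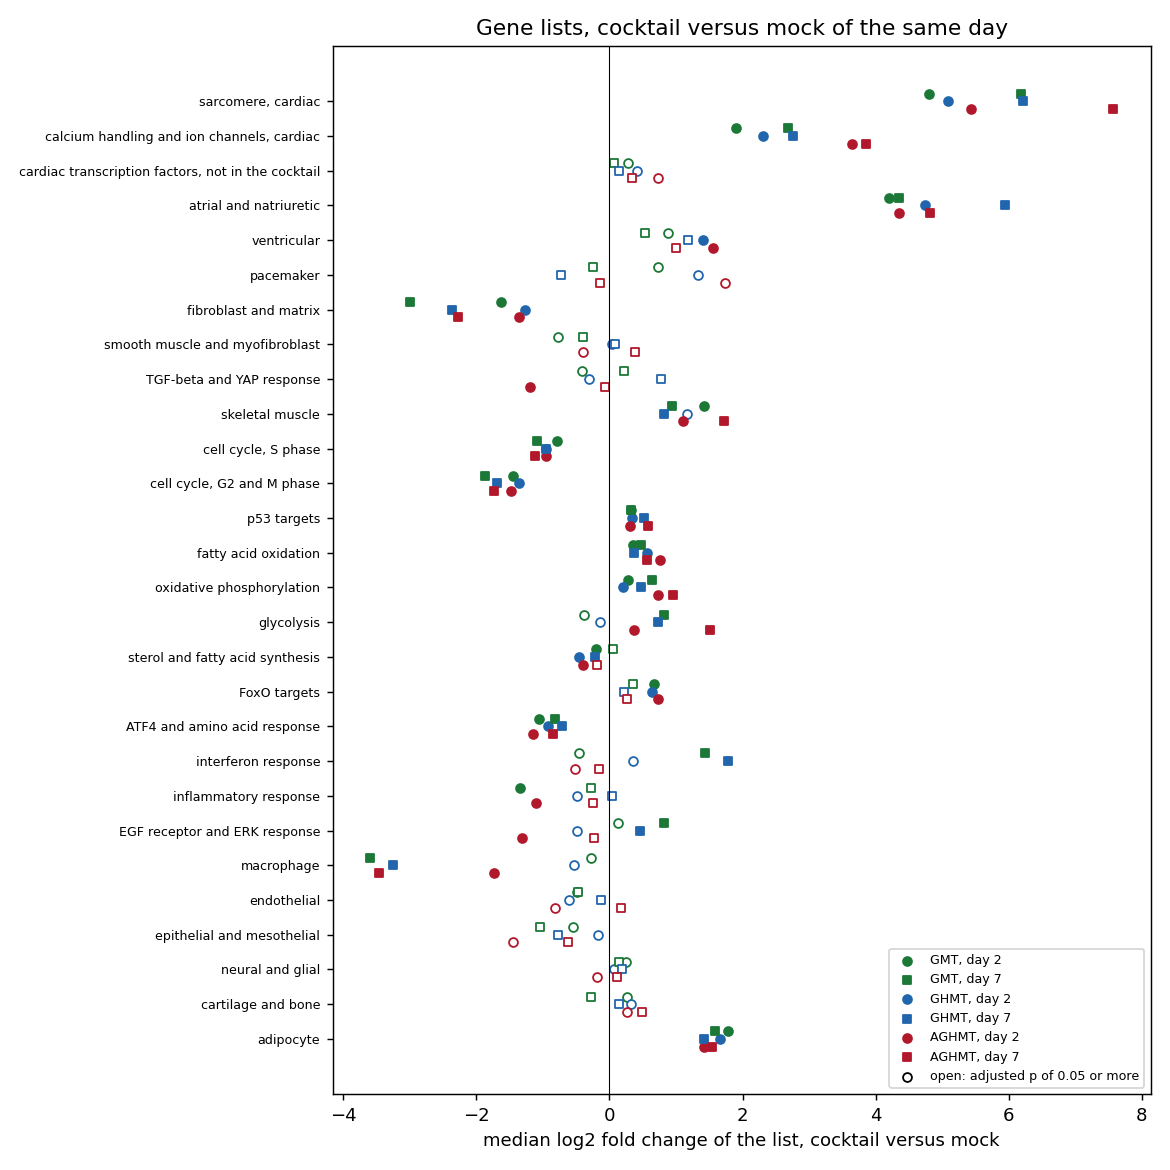
Median log2 fold change of each of the 28 gene lists, cocktail against the mock of the same day, for the 3 cocktails. Circles are day 2 and squares day 7, and open symbols have an adjusted p of 0.05 or more in the camera test. The sarcomere list lies furthest to the right, from 4.81 to 7.57, and the fibroblast and matrix list to the left of 0 in all 6 comparisons.

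The early response was read at day 2. Under AGHMT, the heart genes were already high against the day 2 mock. Of the sarcomere list 36 of 39 members rose and 1 fell (median 5.43, camera, adjusted p = 2.15e-16). Cardiac troponin T, Tnnt2, stood at 7096 ± 1222 against 7.53 ± 0.469 CPM and the Z-disc protein Ldb3 at 673 ± 45.8 against 8.65 ± 0.6700 CPM. Hcn4 (ENSMUSG00000032338, chromosome 9, 58823412-58863175), the pacemaker channel, stood at 885 ± 221 against 0.0878 ± 0.0526 CPM and Casq2 at 1557 ± 24.9 against 0.658 ± 0.116 CPM. Of calcium and channel genes 32 of 35 members rose and 3 fell (camera, adjusted p = 1.91e-09). Their median was 3.64, or 2.95 with the 2 members at 0 counts in a whole group set to the bound of 3 counts per library. Atrial genes rose, with 13 of 17 members higher and 3 lower (camera, adjusted p = 0.000109). In the ventricular list 9 of 12 members rose and 2 fell (camera, adjusted p = 0.00921, or adjusted p = 0.0514 with an estimated correlation). Hey2, a repressor of ventricular myocardium, stood at 23.2 ± 0.389 against 0.829 ± 0.0589 CPM and connexin 43, Gja1, at 934 ± 19.996 against 189.8 ± 4.01 CPM. Of fibroblast and matrix genes 37 of 44 members fell and 6 rose (camera, adjusted p = 7.90e-09, or adjusted p = 0.104 with an estimated correlation). Fbln5 stood at 134 ± 4.38 against 989 ± 58.1 CPM and Lox at 243 ± 15.3 against 2255 ± 146 CPM.

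Growth factor response genes fell under AGHMT at day 2. In the EGF receptor and ERK list 23 of 30 members fell and 4 rose (median -1.32, camera, adjusted p = 4.04e-06). The feedback gene Spry2 stood at 9.27 ± 1.02 against 58.3 ± 1.46 CPM and Dusp6 at 9.54 ± 0.976 against 35.8 ± 1.91 CPM. Of TGF-beta and YAP response genes 16 of 21 members fell and 5 rose (camera, adjusted p = 0.00120, or adjusted p = 0.106 with an estimated correlation). Ctgf stood at 45.7 ± 6.74 against 533 ± 52.5 CPM, unlike Ankrd1, also a heart muscle gene, at 802 ± 106 against 43.2 ± 6.000 CPM. Inflammatory genes were lower, with 19 of 29 members lower and 6 higher (camera, adjusted p = 0.00452, or adjusted p = 0.210 with an estimated correlation). Cyclooxygenase 2, Ptgs2, stood at 3.701 ± 0.0351 against 153 ± 20.9 CPM. Also lower were 18 of 21 macrophage genes (camera, adjusted p = 0.000179, or adjusted p = 0.275 with an estimated correlation). Lyz2 stood at 5.86 ± 1.01 against 27.6 ± 2.22 CPM. All 50 oxidative phosphorylation genes rose (camera, adjusted p = 7.00e-10, or adjusted p = 0.301 with an estimated correlation). In fatty acid oxidation 23 of 25 members rose and 2 fell (camera, adjusted p = 1.89e-06, or adjusted p = 0.131 with an estimated correlation). Acsl1 stood at 216 ± 12.7 against 12.5 ± 1.29 CPM. Among FoxO targets 16 of 25 members rose and 7 fell (camera, adjusted p = 0.0166, or adjusted p = 0.210 with an estimated correlation). Sesn1, a sestrin also induced by p53, stood at 147 ± 6.93 against 14.02 ± 0.964 CPM. The replicate 3 library stood apart from its fellows, with 2.34% of its counts in ribosomal protein genes against 1.73% and 1.74%, and without it the camera calls of skeletal muscle (adjusted p = 0.0787 from 0.0489) and glycolysis (adjusted p = 0.0789 from 0.0457) were lost. Skeletal muscle also lost its call without mock replicate 1 (0.0559) or AGHMT replicate 2 (0.0543), and glycolysis without mock replicate 3 (0.0610). In all, 13255 of 17576 tested genes passed the threshold, 6681 higher and 6574 lower, with 2964 higher and 2676 lower by at least 2-fold (edgeR). Camera called 20 of 28 lists, and sarcomere, calcium, atrial and the EGF receptor and ERK list held with an estimated correlation.

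Under GMT at day 2, 36 of 39 sarcomere genes rose and 1 fell (median 4.81, camera, adjusted p = 6.12e-18). Tnnt2 stood at 2753 ± 75.3 against 7.53 ± 0.469 CPM, Myl7 at 725 ± 16.2 against 0.172 ± 0.0229 CPM and Myom2 at 399 ± 3.54 against 0.487 ± 0.0211 CPM. In the calcium and channel list 27 of 35 members rose and 5 fell (median 1.90, or 1.73 with members at 0 counts set to their bound, camera, adjusted p = 6.44e-07). In the atrial list 12 of 17 members rose and 3 fell (camera, adjusted p = 4.16e-05). Of fibroblast and matrix genes 40 of 44 members fell and 4 rose (median -1.64, camera, adjusted p = 4.91e-15). The collagen VI chain Col6a1 stood at 176 ± 7.798 against 1673 ± 35.6 CPM and Loxl1, a lysyl oxidase of elastic fibres, at 112 ± 5.09 against 553 ± 11.8 CPM. Inflammatory genes were lower, with 20 of 29 members lower and 5 higher (camera, adjusted p = 0.000268, or adjusted p = 0.149 with an estimated correlation). Ptgs2 stood at 7.09 ± 0.794 against 153 ± 20.9 CPM and the chemokine Cxcl12 at 42.2 ± 2.26 against 239 ± 15.97 CPM. In the macrophage list 5 of 21 members fell and 2 rose (4 fell and 2 rose adjusted over the list alone, camera, adjusted p = 0.446). The ATF4 list fell, with 24 of 29 members lower and 5 higher (camera, adjusted p = 8.80e-07, or adjusted p = 0.110 with an estimated correlation). Trib3 stood at 8.899 ± 0.186 against 68.2 ± 5.84 CPM. Pdk4, which restrains pyruvate use and belongs to the fatty acid oxidation and FoxO lists, stood at 68.5 ± 1.02 against 5.45 ± 0.293 CPM. In fatty acid oxidation 20 of 25 members rose and 3 fell (camera, adjusted p = 0.000199, or adjusted p = 0.225 with an estimated correlation). In all, 11791 of 17576 tested genes passed the threshold, 5967 higher and 5824 lower, with 2386 higher and 1951 lower by at least 2-fold (edgeR), and camera called 15 of 28 lists, of which sarcomere, calcium, atrial and fibroblast held with an estimated correlation.

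Under GHMT at day 2 the sarcomere list rose, with 36 of 39 members higher (median 5.08, camera, adjusted p = 6.95e-19). Myl7 stood at 639.8 ± 16.8 against 0.172 ± 0.0229 CPM and Myom2 at 257 ± 6.52 against 0.487 ± 0.0211 CPM. Of calcium and channel genes 29 of 35 members rose and 3 fell (median 2.31, or 2.06 with members at 0 counts set to their bound, camera, adjusted p = 6.79e-09). Hcn4 stood at 412 ± 43.4 against 0.0878 ± 0.0526 CPM and Casq2 at 1677 ± 29.03 against 0.658 ± 0.116 CPM. In the atrial list 13 of 17 members rose and 3 fell (camera, adjusted p = 2.72e-05). In the ventricular list 8 of 12 members rose and 2 fell (camera, adjusted p = 0.0166, or adjusted p = 0.0674 with an estimated correlation). Cited1, a transcriptional coactivator, stood at 45.3 ± 1.38 against 0.126 ± 0.0723 CPM. Of fibroblast and matrix genes 34 of 44 members fell and 7 rose (camera, adjusted p = 8.93e-09, or adjusted p = 0.0936 with an estimated correlation): Dpt, dermatopontin, stood at 2.74 ± 0.222 against 94.3 ± 12.6 CPM and the surface protein Thy1 at 199 ± 4.04 against 1095 ± 34.4 CPM, while Cthrc1, a secreted collagen triple helix protein, rose to 817 ± 37.2 CPM from 116 ± 6.197 CPM. Sterol and fatty acid synthesis fell, with 20 of 29 members lower and 5 higher (camera, adjusted p = 0.000882, or adjusted p = 0.279 with an estimated correlation), but Scd1 stood at 784 ± 27.5 against 221 ± 7.55 CPM. S phase genes fell in 28 of 29 cases (camera, adjusted p = 8.93e-09, or adjusted p = 0.186 with an estimated correlation) and adipocyte genes rose in 15 of 18 (camera, adjusted p = 0.000253, or adjusted p = 0.0674 with an estimated correlation). In all, 11981 of 17576 tested genes passed the threshold, 6126 higher and 5855 lower, with 2511 higher and 2012 lower by at least 2-fold (edgeR). Camera called 14 of 28 lists, and sarcomere, calcium and atrial held with an estimated correlation.

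GHMT against GMT compared cocktails with and without Hand2. At day 7, ventricular genes were higher with Hand2, 7 of 12 (median 0.47, camera, adjusted p = 0.00329). Smooth muscle and myofibroblast genes rose, 14 of 20 with 2 lower (16 and 2 adjusted over the list alone, camera, adjusted p = 1.31e-06). Against mock their median was 0.09 in GHMT and -0.40 in GMT. Cited1 stood at 49.5 ± 1.04 against 3.91 ± 0.328 CPM in GMT and Fhl2, a LIM protein of heart, at 508 ± 31.7 against 170.0 ± 8.79 CPM. Myh11, smooth muscle myosin, stood at 317 ± 22.1 against 67.7 ± 1.24 CPM and Acta2, smooth muscle actin, at 3292 ± 92.9 against 1865 ± 98.8 CPM. Of calcium and channel genes 19 of 35 members rose and 8 fell (camera, adjusted p = 0.00783, or adjusted p = 0.198 with an estimated correlation). Casq2 stood at 2329.6 ± 97.9 against 204 ± 7.79 CPM, Hcn4 at 414 ± 54.7 against 10.5 ± 0.522 CPM and Popdc2 at 268 ± 3.68 against 40.04 ± 1.02 CPM. The sarcomere list was not called, as 17 of 39 members rose and 13 fell (18 rose and 13 fell adjusted over the list alone, camera, adjusted p = 0.135), although Trim55, a muscle ubiquitin ligase outside that list, stood at 82.3 ± 5.904 against 0.458 ± 0.152 CPM. Of fibroblast and matrix genes 27 of 44 members rose and 5 fell (27 rose and 6 fell adjusted over the list alone, camera, adjusted p = 1.31e-06, or adjusted p = 0.198 with an estimated correlation). The collagen V chain Col5a1 stood at 2659.6 ± 157 against 919 ± 19.7 CPM and the matrix proteoglycan Aspn at 87.9 ± 9.202 against 8.697 ± 0.564 CPM. The cartilage and bone list, with the phosphatase Alpl at 31.8 ± 2.09 against 0.652 ± 0.103 CPM, moved the same way, as 7 of 19 members rose and 2 fell (camera, adjusted p = 0.0162, or adjusted p = 0.198 with an estimated correlation). Inflammatory genes were higher, with 17 of 29 members higher and 2 lower (17 higher and 3 lower adjusted over the list alone, camera, adjusted p = 0.000936, or adjusted p = 0.198 with an estimated correlation). Interleukin 6, Il6, stood at 10.2 ± 0.866 against 2.02 ± 0.5400 CPM. In the macrophage list 2 of 21 members rose and 1 fell (1 rose and 1 fell adjusted over the list alone, camera, adjusted p = 0.333). Sterol and fatty acid synthesis was lower, with 22 of 29 members lower and 2 higher (camera, adjusted p = 1.10e-06, or adjusted p = 0.186 with an estimated correlation). The elongase Elovl6 stood at 30.8 ± 1.000 against 77.5 ± 3.06 CPM. Oxidative phosphorylation was lower too, with 24 of 50 members lower (26 lower adjusted over the list alone, camera, adjusted p = 7.45e-05, or adjusted p = 0.725 with an estimated correlation). Pdk4 fell to 70.1 ± 4.31 CPM from 248 ± 4.796 CPM. In all, 6598 of 17576 tested genes passed the threshold, 3290 higher and 3308 lower, with 875 higher and 552 lower by at least 2-fold (edgeR). Camera called 10 of 28 lists, and ventricular and smooth muscle held with an estimated correlation. The replicate 2 library of GHMT at day 7 stood apart, with 2.15% of its counts in ribosomal protein genes against 1.84% and 1.83%.

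At day 2 both lists were again higher with Hand2: 9 of 12 ventricular genes rose (median 1.08, camera, adjusted p = 0.000160), and 15 of 20 smooth muscle genes rose and 3 fell (camera, adjusted p = 1.64e-05). Myh11 stood at 178 ± 11.3 against 26.1 ± 2.09 CPM in GMT, Acta2 at 4056 ± 41.9 against 1360.1 ± 20.1 CPM and Fhl2 at 677 ± 11.5 against 143 ± 2.19 CPM. Casq2 stood at 1677 ± 29.03 against 59.4 ± 2.93 CPM, Hcn4 at 412 ± 43.4 against 32.9 ± 1.82 CPM and Trim55 at 44.6 ± 2.81 against 0.211 ± 0.0564 CPM. Of cardiac transcription factors 14 of 34 members rose and 6 fell (camera, adjusted p = 0.0133, or adjusted p = 0.256 with an estimated correlation). Tbx20 stood at 83.4 ± 6.88 against 11.6 ± 0.682 CPM. Sarcomere members went both ways, with 18 of 39 members higher and 10 lower (18 higher and 11 lower adjusted over the list alone, camera, adjusted p = 0.0489, or adjusted p = 0.301 with an estimated correlation): Myh6 stood at 194 ± 22.9 against 14.4 ± 0.643 CPM and slow troponin I, Tnni1, at 522 ± 27.7 against 35.2 ± 0.362 CPM, but cardiac actin, Actc1, fell to 90.01 ± 5.199 CPM from 331 ± 10.1 CPM. Their median log2 difference was 0.00, below 0 with RLE size factors or CPM on total counts, while their mean was 0.37, and the call was lost without GHMT replicate 2 (adjusted p = 0.0583). Skeletal muscle genes fell, 14 of 22 with 1 higher (15 and 2 adjusted over the list alone, camera, adjusted p = 0.00511, or adjusted p = 0.139 with an estimated correlation). Interferon genes were higher with Hand2, 34 of 37 (35 adjusted over the list alone, median 0.87, camera, adjusted p = 1.43e-05, or adjusted p = 0.576 with an estimated correlation). Against the day 2 mock the list median was 0.35 in GHMT and -0.47 in GMT. The chemokine Cxcl10 stood at 112 ± 25.4 against 23.1 ± 5.61 CPM and Oasl1 at 100.1 ± 16.1 against 27.6 ± 3.304 CPM. In the macrophage list 5 of 21 members fell (4 fell adjusted over the list alone, camera, adjusted p = 0.163, or adjusted p = 0.0445 without GMT replicate 2). Glycolysis genes rose, 14 of 23 with 4 lower (camera, adjusted p = 0.00511, or adjusted p = 0.516 with an estimated correlation). The glucose transporter Slc2a1 stood at 150.3 ± 3.66 against 54.002 ± 0.654 CPM. The EGF receptor and ERK list fell, with 20 of 30 members lower and 7 higher (camera, adjusted p = 0.00511, or adjusted p = 0.207 with an estimated correlation). Dusp6 stood at 25.8 ± 1.48 against 59.2 ± 1.33 CPM, unlike Spry4 at 101 ± 1.32 against 30.2 ± 0.725 CPM. In all, 7872 of 17576 tested genes passed the threshold, 4055 higher and 3817 lower, with 933 higher and 787 lower by at least 2-fold (edgeR), relative to an all-gene median that CPM on total counts moved by -0.12. Camera called 12 of 28 lists, and ventricular and smooth muscle held with an estimated correlation. The replicate 3 library of GHMT at day 2 stood apart, with 2.39% of its counts in ribosomal protein genes against 2.16% and 2.18%.

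AGHMT against GHMT showed what differed between cocktails with and without Akt1. At day 7 the sarcomere, calcium, pacemaker and skeletal muscle lists were higher with Akt1. The smooth muscle list was not called, as 9 of 20 members rose and 5 fell (camera, adjusted p = 0.166), nor was the atrial list, where 8 of 17 members rose and 7 fell (8 rose and 8 fell adjusted over the list alone, camera, adjusted p = 0.795). Of the sarcomere list 24 of 39 members rose and 5 fell (median 0.47, camera, adjusted p = 6.64e-05). Myh6 stood at 4610.3 ± 176 against 887 ± 81.9 CPM in GHMT, Actn2 at 466 ± 11.3 against 119 ± 6.18 CPM and Xirp2, a protein of intercalated discs, at 39.3 ± 3.97 against 2.08 ± 0.351 CPM. Calcium and channel genes were higher, with 21 of 35 members higher and 4 lower (21 higher and 5 lower adjusted over the list alone, camera, adjusted p = 0.000180). Trdn stood at 156 ± 3.01 against 27.4 ± 1.49 CPM and Atp2a2, the calcium pump SERCA2, at 3449 ± 76.1 against 1683 ± 89.5 CPM. Pacemaker genes rose, with 12 of 17 members higher and 1 lower (13 higher and 1 lower adjusted over the list alone, camera, adjusted p = 8.86e-05). Against the day 7 mock the median of this list was -0.14 under AGHMT and -0.72 under GHMT, so neither lay above it. The pacemaker and calcium lists overlap and are not independent results. Contactin 2, Cntn2, stood at 72.4 ± 4.88 against 14.6 ± 1.65 CPM and Igfbp5 at 1490.0 ± 121 against 333 ± 29.2 CPM. Skeletal muscle genes followed, with 13 of 22 members higher and 1 lower (camera, adjusted p = 0.000222). Myl1 stood at 740.3 ± 36.1 against 23.1 ± 3.09 CPM and skeletal actin, Acta1, at 100.3 ± 7.67 against 17.4 ± 3.23 CPM. Of cardiac transcription factors 14 of 34 members rose and 6 fell (16 rose and 8 fell adjusted over the list alone, camera, adjusted p = 0.0493, or adjusted p = 0.274 with an estimated correlation). Smyd1 stood at 144 ± 5.44 against 23.3 ± 1.102 CPM and Ppargc1a, a coactivator of mitochondrial genes, at 34.8 ± 2.57 against 5.37 ± 0.383 CPM. Of ventricular genes 7 of 12 members rose and 1 fell (7 rose and 2 fell adjusted over the list alone, camera, adjusted p = 0.0493, or adjusted p = 0.109 with an estimated correlation). The call of the transcription factors was lost without GHMT replicate 2 or 3 or AGHMT replicate 2 or 3 (adjusted p = 0.0516 to 0.0681), and that of the ventricular list without GHMT replicate 1 or 3 or AGHMT replicate 2 or 3 (adjusted p = 0.0501 to 0.0552) or with offsets for GC content and length (adjusted p = 0.0672). Gata4 and Tbx5 counts, viral and endogenous together, were lower with Akt1, at 633 ± 5.18 against 1142 ± 85.9 CPM and 1730.2 ± 25.9 against 2746 ± 62.01 CPM.

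In the same comparison the EGF receptor and ERK list fell, with 25 of 30 members lower and 2 higher (median -0.87, camera, adjusted p = 4.18e-11). Egr1, an immediate early gene, stood at 33.5 ± 1.87 against 106 ± 4.74 CPM, Spry4 at 47.05 ± 0.902 against 121 ± 2.94 CPM and Dusp6 at 34.3 ± 0.299 against 86.2 ± 1.74 CPM. TGF-beta and YAP response genes fell too, with 18 of 21 members lower and 1 higher (camera, adjusted p = 1.18e-07). The receptor kinase Axl stood at 333 ± 4.94 against 727 ± 30.98 CPM and Tgfb1 at 25.01 ± 0.238 against 55.5 ± 1.73 CPM. Interferon genes were lower, with 35 of 37 members lower (median -1.82, camera, adjusted p = 4.76e-15, or adjusted p = 0.274 with an estimated correlation). Irf7 stood at 27.8 ± 5.61 against 125 ± 12.9 CPM, Oas3 at 13.3 ± 2.797 against 72.8 ± 3.06 CPM and Rsad2, viperin, at 4.97 ± 2.91 against 42.3 ± 4.902 CPM. In the macrophage list 4 of 21 members fell (2 fell adjusted over the list alone, camera, adjusted p = 0.0772, or adjusted p = 0.0154 without AGHMT replicate 1). Oxidative phosphorylation genes rose in 49 of 50 cases (median 0.54, camera, adjusted p = 5.38e-16, or adjusted p = 0.274 with an estimated correlation). Atp5a1, of ATP synthase, stood at 1074 ± 24.8 against 670.2 ± 14.6 CPM and Cox7a1 at 23.97 ± 0.567 against 3.102 ± 0.263 CPM. Of glycolysis genes 19 of 23 members rose and 3 fell (camera, adjusted p = 1.18e-07, or adjusted p = 0.120 with an estimated correlation). Pfkm stood at 215 ± 5.07 against 74.4 ± 0.625 CPM and pyruvate dehydrogenase kinase 1, Pdk1, at 108 ± 1.84 against 30.2 ± 1.61 CPM. In fatty acid oxidation 17 of 25 members rose and 4 fell (camera, adjusted p = 0.000686, or adjusted p = 0.297 with an estimated correlation). In all, 8553 of 17576 tested genes passed the threshold, 4401 higher and 4152 lower, with 1039 higher and 522 lower by at least 2-fold (edgeR). Camera called 12 of 28 lists, and sarcomere, calcium, pacemaker, TGF-beta and YAP, skeletal muscle and the EGF receptor and ERK list held with an estimated correlation.

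At day 2, smooth muscle, TGF-beta and ERK genes were lower with Akt1 than without. Of smooth muscle and myofibroblast genes 14 of 20 members fell and 2 rose (median -0.70, camera, adjusted p = 6.64e-06). Tagln, transgelin, stood at 291 ± 43.1 against 873 ± 19.9 CPM in GHMT and the Z-disc protein Pdlim3 at 6.98 ± 0.443 against 38.95 ± 2.01 CPM. Of TGF-beta and YAP response genes 17 of 21 members fell and 1 rose (camera, adjusted p = 9.88e-08). Cyr61 stood at 98.7 ± 9.05 against 421 ± 7.001 CPM and Amotl2 at 50.5 ± 1.18 against 189 ± 2.39 CPM, both known YAP targets. In the EGF receptor and ERK list 24 of 30 members fell and 1 rose (camera, adjusted p = 1.82e-10). Spry4 stood at 31.7 ± 1.44 against 101 ± 1.32 CPM and the phosphatase Dusp4 at 8.999 ± 0.397 against 29.99 ± 1.72 CPM. Interferon genes were lower, with 30 of 37 members lower (camera, adjusted p = 2.03e-05, or adjusted p = 0.543 with an estimated correlation). Ifit2 stood at 148 ± 27.96 against 441 ± 57.8 CPM. Inflammatory genes were lower too, with 14 of 29 members lower and 3 higher (camera, adjusted p = 0.00632, or adjusted p = 0.342 with an estimated correlation). The macrophage growth factor Csf1 stood at 143 ± 4.55 against 275 ± 8.78 CPM. Macrophage markers moved with them, with 19 of 21 members lower (median -1.29, camera, adjusted p = 2.03e-05, or adjusted p = 0.342 with an estimated correlation). Csf1r, the receptor of Csf1, stood at 3.44 ± 0.275 against 9.82 ± 0.927 CPM. Its mean in the day 2 mock was 3.62 CPM, so this member stood above mock in GHMT and near mock in AGHMT. Lyz2 had means of 5.86 CPM in AGHMT, 11.9 CPM in GHMT and 27.6 CPM in that mock. Oxidative phosphorylation genes rose in 49 of 50 cases (median 0.53, camera, adjusted p = 1.74e-15, or adjusted p = 0.342 with an estimated correlation). Cytochrome c1, Cyc1, stood at 159 ± 9.61 against 96.7 ± 3.01 CPM. Of glycolysis genes 15 of 23 members rose and 5 fell (camera, adjusted p = 0.00404, or adjusted p = 0.397 with an estimated correlation). Ldhb stood at 359.6 ± 47.9 against 137 ± 8.86 CPM. Calcium and channel genes were higher, with 20 of 35 members higher and 5 lower (20 higher and 6 lower adjusted over the list alone, camera, adjusted p = 0.00649, or adjusted p = 0.235 with an estimated correlation). Trdn stood at 39.1 ± 1.55 against 8.798 ± 0.107 CPM. The sarcomere list was not called (camera, adjusted p = 0.0819). In all, 9259 of 17576 tested genes passed the threshold, 4521 higher and 4738 lower, with 932 higher and 954 lower by at least 2-fold (edgeR), or 6944 genes when the compared libraries were fitted alone. Camera called 13 of 28 lists, and smooth muscle, TGF-beta and YAP, and the EGF receptor and ERK list held with an estimated correlation. Skeletal muscle lost its call without AGHMT replicate 3, the library that stood apart (adjusted p = 0.0886 from 0.0446), or without replicate 2 (0.0526).

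**Figure D3:**
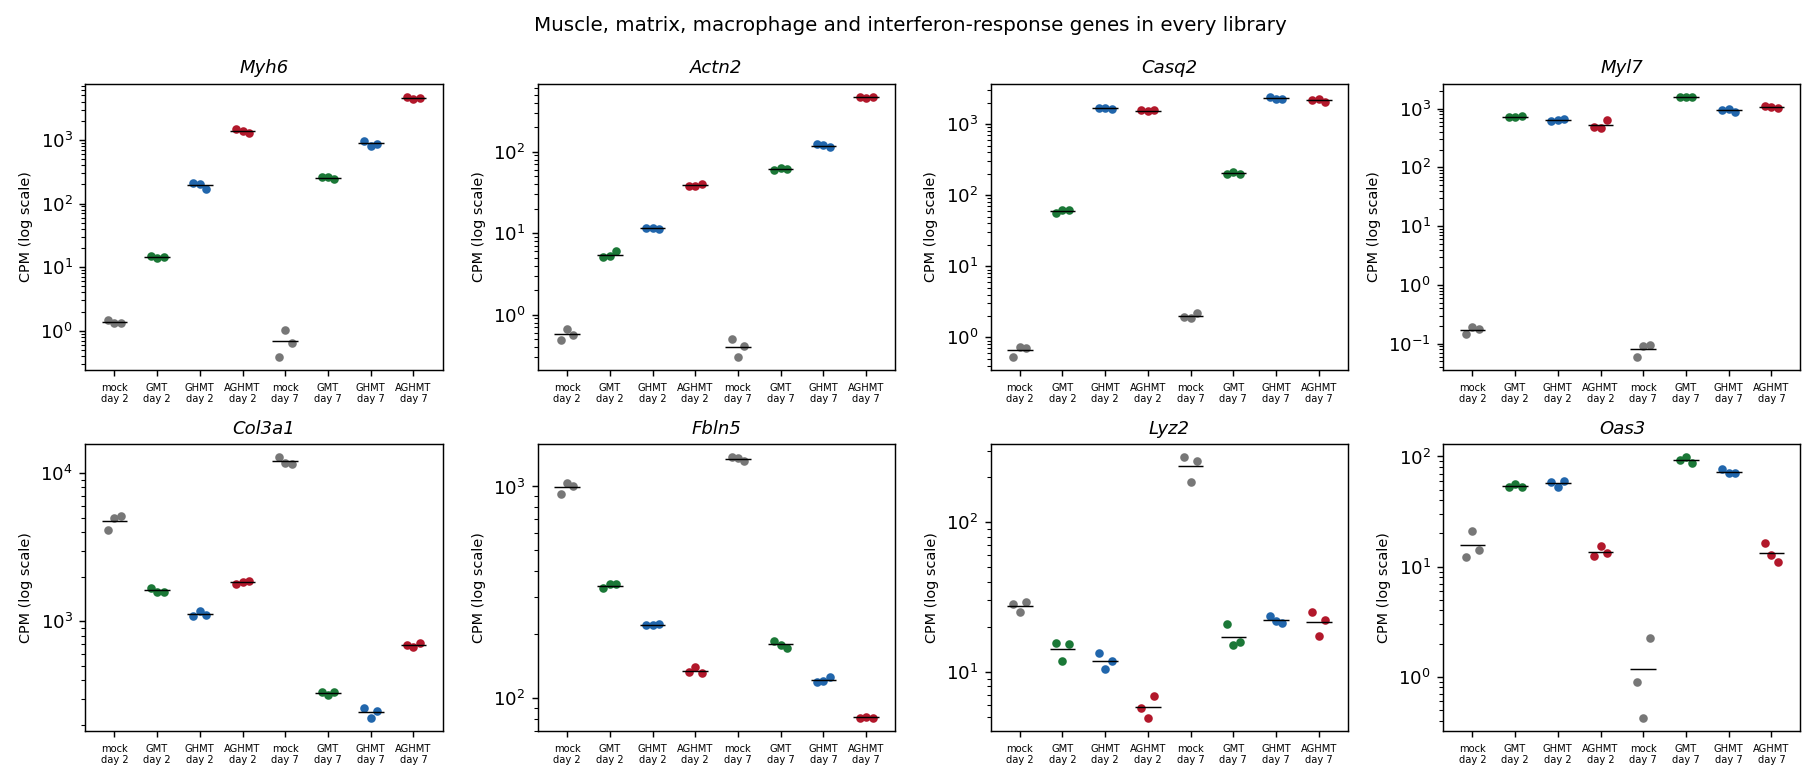
Level of 8 genes in each of the 24 libraries, in CPM on a log axis, grouped by cocktail and day, where points are libraries and lines are group means. Myh6, Actn2, Casq2 and Myl7 lie above mock under each cocktail, Col3a1 and Fbln5 lie below the day 7 mock, Lyz2 peaks in the day 7 mock, and Oas3 is lowest there.

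Mock cultures themselves changed between day 2 and day 7, which sets the baseline of the later comparisons. All 37 interferon genes fell (median -3.13, camera, adjusted p = 3.65e-23, or adjusted p = 0.209 with an estimated correlation). Cxcl10 stood at 3.91 ± 1.56 at day 7 against 143 ± 56.7 CPM at day 2, Mx1 at 0.798 ± 0.375 against 26.6 ± 10.2 CPM and Oas1a, of a family with similar copies, at 2.99 ± 0.9902 against 40.5 ± 6.72 CPM. All 21 macrophage genes rose (median 2.95, camera, adjusted p = 3.42e-12, or adjusted p = 0.209 with an estimated correlation). Lyz2 stood at 239 ± 45.3 against 27.6 ± 2.22 CPM and Mrc1 at 50.1 ± 10.2 against 1.51 ± 0.199 CPM. Epithelial and mesothelial markers rose too, with 11 of 15 members higher and 2 lower (median 1.29, camera, adjusted p = 0.000543, or adjusted p = 0.209 with an estimated correlation). Fibroblast and matrix genes rose, with 32 of 44 members higher and 6 lower (camera, adjusted p = 1.27e-07, or adjusted p = 0.209 with an estimated correlation). Eln stood at 1688 ± 320.0 against 37.9 ± 6.88 CPM, decorin, Dcn, at 909.8 ± 29.6 against 163 ± 25.5 CPM and lumican, Lum, at 412 ± 15.3 against 54.5 ± 11.9 CPM. Glycolysis genes fell, 19 of 23 with 4 higher (camera, adjusted p = 4.58e-09, or adjusted p = 0.209 with an estimated correlation). The lactate transporter Slc16a3 stood at 15.6 ± 1.64 against 69.4 ± 6.37 CPM and Hk2 at 21.3 ± 0.922 against 53.6 ± 4.71 CPM. G2 and M phase genes fell in 27 of 29 cases (camera, adjusted p = 5.09e-07, or adjusted p = 0.391 with an estimated correlation). Mef2c rose to 33.1 ± 2.25 CPM from 13.6 ± 0.728 CPM. In all, 9754 of 17576 tested genes passed the threshold, 5217 higher and 4537 lower, with 1479 higher and 955 lower by at least 2-fold (edgeR). Camera called 12 of 28 lists, of which none held with an estimated correlation, where 6 lists had an unadjusted p under 0.05. Fry called 26.

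Whether an effect differed between the days was tested as the difference of the 2 effects, each against the mock of its own day. Sarcomere genes gained more at day 7 under each cocktail. Under GMT 23 of 39 members rose and 5 fell (23 rose and 6 fell adjusted over the list alone, median difference 1.27, camera, adjusted p = 6.86e-08), with Myh6 at a difference of 5.15 ± 0.28 and Actn2 at 4.01 ± 0.24. Under GHMT 23 of 39 members rose and 4 fell (median 1.12, camera, adjusted p = 1.73e-06). Actc1 differed by 3.72 ± 0.19. Under AGHMT 25 of 39 members rose and 3 fell (median 1.06, camera, adjusted p = 9.70e-08). Myom2 differed by 3.45 ± 0.19. Not all members followed, as Sorbs2, of Z-discs, differed by -1.47 ± 0.09 under GMT and -1.74 ± 0.09 under GHMT. Mef2c stood less far above mock at day 7 than at day 2, by -2.02 ± 0.07, -1.89 ± 0.07 and -2.07 ± 0.07 under GMT, GHMT and AGHMT. Part of this was its rise in mock, by 1.29 ± 0.06, and under the cocktails its level fell from 2799.7 ± 41.7 CPM, 3054 ± 56.1 CPM and 2819 ± 163 CPM to 1681 ± 50.3 CPM, 2016 ± 33.9 CPM and 1643 ± 20.7 CPM. The EGF receptor and ERK list was higher at day 7 than at day 2 relative to mock, with 21 of 30 members higher and 5 lower (22 higher and 5 lower adjusted over the list alone) under GMT (median 0.48, camera, adjusted p = 4.55e-05), 20 of 30 members higher and 4 lower under GHMT (median 0.65, camera, adjusted p = 2.19e-06) and 22 of 30 members higher and 3 lower (23 higher and 3 lower adjusted over the list alone) under AGHMT (median 0.88, camera, adjusted p = 1.36e-07). Dusp6 differed by 1.66 ± 0.07, 2.19 ± 0.07 and 2.29 ± 0.08 in that order.

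Fibroblast and matrix genes were lower at day 7 than at day 2 relative to mock, with 35 of 44 members lower and 4 higher (35 lower and 5 higher adjusted over the list alone) under GMT (median -1.22, camera, adjusted p = 1.41e-13), 34 of 44 members lower and 6 higher under GHMT (camera, adjusted p = 3.10e-11, or adjusted p = 0.0651 with an estimated correlation) and 31 of 44 members lower and 9 higher under AGHMT (camera, adjusted p = 9.70e-08, or adjusted p = 0.117 with an estimated correlation). Eln differed by -8.45 ± 0.29, -8.52 ± 0.27 and -7.17 ± 0.26, and Eln had risen in mock. Glycolysis genes moved up, with 20 of 23 members higher and 1 lower under GMT (median 1.14, camera, adjusted p = 4.65e-13), 19 of 23 members higher and 2 lower (20 higher and 2 lower adjusted over the list alone) under GHMT (camera, adjusted p = 2.03e-09, or adjusted p = 0.0705 with an estimated correlation) and 19 of 23 members higher and 1 lower under AGHMT (camera, adjusted p = 3.33e-10, or adjusted p = 0.0900 with an estimated correlation). Hk2 differed by 1.84 ± 0.08, 2.16 ± 0.08 and 2.91 ± 0.08. Glycolysis had fallen in mock. Interferon genes differed by a median of 1.99 under GMT (camera, adjusted p = 1.07e-12, or adjusted p = 0.346 with an estimated correlation) and 1.28 under GHMT (camera, adjusted p = 1.87e-07, or adjusted p = 0.481 with an estimated correlation), against 0.38 under AGHMT (camera, adjusted p = 0.109, 0.000953 as the adjusted p without mock day 7 replicate 3, 0.0322 without mock day 2 replicate 1 and 0.0324 without AGHMT day 7 replicate 3). Macrophage markers differed by medians of -3.37 (camera, adjusted p = 1.10e-11, or adjusted p = 0.0825 with an estimated correlation), -2.52 (camera, adjusted p = 2.73e-09, or adjusted p = 0.112 with an estimated correlation) and -1.70 (camera, adjusted p = 2.85e-06, or adjusted p = 0.243 with an estimated correlation). Within the cocktails the macrophage list moved between the days by medians of -0.31, 0.42 and 1.15, and in mock by 2.95, while the interferon list moved by -3.13 in mock. TGF-beta and YAP response genes were higher, with 14 of 21 members higher and 4 lower (camera, adjusted p = 0.000820, or adjusted p = 0.0825 with an estimated correlation), 14 of 21 members higher and 3 lower (16 higher and 3 lower adjusted over the list alone, camera, adjusted p = 5.76e-05, or adjusted p = 0.0651 with an estimated correlation) and 14 of 21 members higher and 2 lower (14 higher and 3 lower adjusted over the list alone, camera, adjusted p = 4.57e-05, or adjusted p = 0.0625 with an estimated correlation). The smooth muscle list, not called against mock at either day (medians -0.40 at day 2 and 0.38 at day 7), was higher at day 7 than at day 2 relative to mock under AGHMT, with 13 of 20 members higher and 6 lower (camera, adjusted p = 0.00140, or adjusted p = 0.106 with an estimated correlation). Tagln differed by 2.35 ± 0.10. The day differences numbered 8707 genes (4265 higher and 4442 lower) under GMT, 8667 genes (4095 higher and 4572 lower) under GHMT and 8941 genes (4361 higher and 4580 lower) under AGHMT (edgeR). Camera called 14, 11 and 13 of 28 lists, and with an estimated correlation sarcomere and the EGF receptor and ERK list held under each cocktail, and fibroblast and glycolysis under GMT.

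The calls of both days were compared within each cocktail, since each day had its own mock libraries. Under GMT, 8530 genes were called in the same direction at both days, 4411 higher, where independent lists would share 2211, and 4119 lower, where they would share 2095. Under GHMT, 8471 genes were called in the same direction at both days, 4412 higher, where independent lists would share 2226, and 4059 lower, where they would share 2086. Under AGHMT, 9929 genes were called in the same direction at both days, 5099 higher, where independent lists would share 2582, and 4830 lower, where they would share 2506. Across the 17576 tested genes, which are not independent replicates, the log2 fold changes of day 2 and day 7 correlated with Pearson's r of 0.76 and Spearman's rho of 0.68 under GMT, 0.76 and 0.68 under GHMT, and 0.79 and 0.74 under AGHMT. Casq2, Myom2 and the cocktail factors Gata4, Mef2c and Tbx5 were higher than mock at both days under each cocktail.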

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

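The count of genes called in opposite directions at both days was chosen after results had been seen, while the tests of the difference between days were planned.

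The effect of each cocktail differed between day 7 and day 2 for several lists that passed camera with either correlation, each effect being set against the mock of its own day. The sarcomere list gained a median log2 of 1.27 under GMT, 1.12 under GHMT and 1.06 under AGHMT. The EGF receptor and ERK list gained 0.48, 0.65 and 0.88 in the same order. Under GMT the fibroblast and matrix list had a median difference of -1.22 and the glycolysis list one of 1.14. Mock itself moved between the days, by medians of 0.06 in the sarcomere, -0.25 in the EGF receptor and ERK, 0.55 in the fibroblast and matrix and -0.82 in the glycolysis list, and these moves are part of the differences.

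Genes called in opposite directions against mock at both days numbered 1177 under GMT, 1204 under GHMT and 1142 under AGHMT. Of these, 578, 622 and 620 were higher at day 2 and lower at day 7, and 599, 582 and 522 the other way. At both days 127, 138 and 158 of them differed from mock by at least 2-fold.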

How the results depend on the processing

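Offsets for GC content and length, and leaving out the 3 libraries furthest from their groups, were chosen after the data had been seen. Every count of called genes (14 comparisons), every overlap between days and the factor count of 24 stayed within 1.5 times its value under every alternative run, single libraries left out included. AGHMT against mock at day 7 gave 13630 genes with DESeq2, 13501 with RLE size factors, 14256 without the filter, 13850 with the offsets and 13091 to 13233 with single libraries left out. The largest shift in the share of higher calls was 5.25 percentage points. List counts stayed within 1.5 times with RLE size factors, single libraries left out, the offsets and the 3 libraries left out. With an estimated correlation camera called 4, 4 and 5 lists for GMT, GHMT and AGHMT against mock at day 7 and 4, 3 and 4 at day 2. It called 2 and 2 for GHMT against GMT at days 7 and 2, 6 and 3 for AGHMT against GHMT, 4, 2 and 2 for the day differences, and 0 in mock (6 with an unadjusted p under 0.05). Fry, which does not compare with other genes, called 26, 28 and 26 lists at day 7, 26 and 25 for GMT and GHMT at day 2, 18 and 21 for GHMT against GMT, 22 and 22 for AGHMT against GHMT, 23, 23 and 23 for the day differences and 26 in mock. Estimated correlations widen the test of a list; the cause of single losses was not tested. Of 389 pairs of a gene chosen for naming and a comparison, no direction reversed. Depth limits genes at a few counts, and folds are bounds only where a whole group was at 0 counts.

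The replicate numbers share only a number: over 84 pairs of same-numbered libraries the correlation of deviations ran from -0.213 to 0.274, with a median of 0.0017 and 1 over 0.1, and 5 of 24 libraries matched their own number best. With the replicate block, AGHMT against mock at day 7 gave 13487 genes and AGHMT against GHMT at day 7 gave 16 lists against 12, and the FoxO targets of GHMT against mock at day 2 lost their call (camera, adjusted p = 0.0512), as did oxidative phosphorylation in mock (camera, adjusted p = 0.0558).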

Other observations

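The tests of the mislabelled library, of both macrophage explanations, of ribosomal protein genes and of the Akt1 effect were chosen after the results had been seen, those of GC content and length after the data had been seen but before their own values, and only the counts of other splits were planned.

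Genes outside the heart lists were among those that moved most. Mcpt4, a mast cell protease of a family with similar copies, was at 0 counts in mock at both days and reached 172 ± 5.899 CPM in AGHMT at day 7, at least 1879-fold higher. Gtsf1, a germ cell gene of piRNA silencing, reached 47.9 ± 1.96 CPM there, at least 524-fold higher. At day 2 the histamine receptor Hrh3 was at least 724-fold higher under AGHMT, angiotensinogen, Agt, stood at 345 ± 35.3 against 0.0551 ± 0.0711 CPM, and under GMT the receptor Gpr83 was at least 931-fold higher and the secretory protein Scg2 stood at 629 ± 12.8 against 0.392 ± 0.0368 CPM. Genes that fell furthest included the angiotensin receptor Agtr2, at 0.954 ± 0.848 against 557 ± 39.6 CPM in AGHMT and mock at day 7, the matricellular gene Nov, at 3.38 ± 0.483 against 1058 ± 53.9 CPM, and at day 2 the interleukin 33 receptor Il1rl1, at 6.401 ± 0.475 against 496 ± 46.3 CPM, and osteopontin, Spp1, at 14.1 ± 2.89 against 655 ± 34.3 CPM. With Akt1, vasopressin (Avp) stood at 6.53 ± 0.744 against 0.0755 ± 0.0400 CPM in GHMT at day 7, and tyrosine hydroxylase (Th) at 5.59 ± 0.726 against 0.243 ± 0.137 CPM at day 2.

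The AGHMT day 2 library of replicate 3 stood apart from its group, with 96 ribosomal protein genes higher by a median log2 of 0.44. GC content and gene length explained 16.7% of the variance of its deviations. That variance also holds ordinary noise between replicates. The root mean square log2 distance to its fellows was 0.396, and 0.309 for the furthest library of GHMT at day 2. The share of what set it apart that GC content and length explain is therefore not known from this value. A wrong label was first tested as the distance to its own group over that to the nearest other group, GHMT at day 2, which gave 0.563 and decided nothing. After that value had been seen, the test was replaced by the distance to that group over the distance of its furthest library to its fellows, which gave 2.28, above the bound of 2, and argues against a wrong label among these 8 groups. No biological explanation was tested, and what set this library apart stays open.

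Macrophage markers were lower under each cocktail than in mock at day 7. The macrophage list rose in mock by a median log2 of 2.95 between the days, with Lyz2 from 27.6 to 239 CPM, so a rise of macrophages in the mock cultures is a candidate explanation. Epithelial and mesothelial markers also rose in mock (median 1.29, camera, adjusted p = 0.000543, or adjusted p = 0.209 with an estimated correlation), so the change was not limited to macrophages. Whether macrophages also fell below the day 2 mock stays open, since the day 7 cocktails lay at medians of -0.60 (GMT), -0.15 (GHMT) and -0.51 (AGHMT) against it. At day 2, AGHMT lay below that mock, with 18 of 21 members lower (median -1.73, camera, adjusted p = 0.000179, or adjusted p = 0.275 with an estimated correlation), while GHMT lay at -0.53 (camera, adjusted p = 0.107) and GMT at -0.27 (camera, adjusted p = 0.446) without a call. Of 21 markers, 17 were over 1 CPM in mock at day 2, and none is in another list.

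Oxidative phosphorylation genes were higher in AGHMT than in GHMT at both days. Offsets for GC content and length left 91.6% of the median at day 2 (0.53 to 0.48) and more at day 7 (0.54 to 0.53), which argues against them as the whole cause. Ribosomal protein genes, also short and abundant, had medians of -0.27 at day 2 and -0.30 at day 7, against a general gain of such transcripts. An effect of the added Akt1 may account for the difference, but it cannot be told apart from other differences between these cultures, and with an estimated correlation the lower adjusted p of the days was 0.274 (camera).

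Other splits of the libraries were counted with edgeR and camera fitted on the compared libraries. With 3 against 3 there are 10 splits, too few for a share under 0.05. In any other split both groups hold libraries of both conditions, so the difference between conditions enters the spread within groups. A count of 0 genes there does not speak against chance. The real split gave 12722, 12009 and 13259 genes for GMT, GHMT and AGHMT at day 7, 12118, 11696 and 11697 at day 2, 6847 and 8610 for GHMT against GMT at days 7 and 2, 8738 and 6944 for AGHMT against GHMT, and 9943 in mock, against at most 0 in any other split, so 1 of 10 was as large each time. For lists the real and the highest other counts were 16 and 14, 15 and 13, and 14 and 16 (5 of 10 as many) at day 7, 15 and 14, 14 and 14 (3 of 10), and 19 and 17 at day 2, 8 and 7, 7 and 6 for GHMT against GMT, 15 and 13, 12 and 12 (2 of 10) for AGHMT against GHMT, and 11 and 9 in mock. For the day differences 100 of 200 splits were drawn. The real split gave 9726, 8814 and 8066 genes under GMT, GHMT and AGHMT, where 1 of 100 was as large, and the highest others, 7755, 6091 and 6083, kept the real day 7 groups and mixed day 2. Splits that mixed both days gave 0 genes each time, since the difference between cocktail and mock then enters the spread within groups. The gene counts of these splits therefore do not decide on chance for the day differences. Lists were called in such splits too. The list counts of 11, 11 and 12 were matched by 51, 55 and 52 of 100 splits, with highest others of 16, 15 and 20. Such splits keep part of the cocktail effect, so list counts do not decide either.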
